A study of Mus musculus with 6 samples.

How the data were processed

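Gene expression was measured in whole-heart tissue of mice at postnatal day 7 in 2 groups of 3 libraries, a control group and a group named GR-cKO, in which the glucocorticoid receptor gene (Nr3c1) is deleted in cardiomyocytes. The labels call the 3 libraries of a group biological replicates. They give neither the deleted exon, the Cre line nor the genotype of the control animals. Per the labels' protocols, hearts were homogenised, RNA was extracted with the NucleoSpin RNA II kit, and libraries were made from 100 ng of total RNA with the QuantSeq 3′ mRNA-Seq FWD kit, which sequences the 3′ end of polyadenylated transcripts. A read count from such a library follows the number of transcripts and not their length, and it reads only the 3′ end of each gene.

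The deposited files hold counts, whole numbers of reads per Ensembl mouse gene, 1 library per file, not normalized and not pooled. Per the submitters' processing notes, the tools were bcl2fastq, cutadapt 1.16, FastQC 0.11.7, MultiQC 1.5, STAR 2.5.4a, featureCounts 1.6.2 and DESeq2 1.18.1, with the GRCm38 build. The annotation release, the strand setting of the counting and the read filters are not given in the sources used here. A gene that overlaps another gene on the opposite strand, or that has near-identical copies, therefore has an uncertain count. Each file has 52649 rows, of which 52550 are mouse genes, 92 are ERCC and 7 are SIRV spike-in transcripts. Gene symbols and coordinates came from GENCODE M21, which uses the same build, and 52403 mouse gene identifiers matched a symbol. The other 147 took at most 0.00893% of a library's reads.

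Spike-in rows were left out of library sizes and tests. With edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, genes were filtered with filterByExpr by group, which kept 14860 genes, and libraries were scaled with the trimmed mean of M-values (TMM). Genotype was tested with the edgeR quasi-likelihood F test with robust dispersion, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values of genes come from this test unless another tool is named. CPM values are reads of a gene relative to the library's reads of all tested genes and are scaled by TMM. The single-library CPM of genes named outside the rule are relative to all mouse gene reads, with the same TMM factors. The log2 CPM values used a prior count of 2. Fold changes are GR-cKO over control. The distance between a log2 fold change and each bound of its 95% interval follows the model's standard error (SE). These intervals cover the spread between hearts. Reads without molecular identifiers are not independent molecules, and no interval for counting error alone was used.

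Before the data were examined, 35 lists were fixed, 20 of pathways and gene programmes and 15 of cell type markers. The main lists, also chosen then, were glucocorticoid-responsive genes, respiratory chain complex I, fatty acid uptake and oxidation, and S phase and mitosis genes. A further marker list of sex-linked genes served only to call the sex of each library. Lists with at least 5 tested members, 33 in all, were tested with limma's camera on log2 CPM, 2-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The lung and liver lists had too few tested members. Members were also adjusted over their list alone, with no correction across the 35 lists, so such a pass is weaker than 1 over all genes. Camera asks whether a list's genes move relative to all other genes. The same lists were tested with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in 1 direction. With an estimated correlation camera uses only the residual degrees of freedom of the 6 libraries, far fewer than with the preset one. In that form the smallest unadjusted p of the 33 lists was 0.0553, so none could pass. A call lost there does not show that a list did not move. A list score is the mean log2 CPM of the list's genes in a library, relative to the mean of the 6 libraries. Single values per library, such as shares of reads, were compared with 2-sided exact permutation tests, which cannot give a p below 0.1 for 3 libraries against 3.

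The rule for named genes was also fixed in advance: Nr3c1, 14 genes of glucocorticoid action and heart maturation, the strongest called genes in each direction, and up to 3 members of smallest p from each list past the threshold. Because fewer than 5 genes passed, the strongest called genes were replaced, as the rule provided, by the 10 genes of smallest p with a mean CPM of at least 5. In all 33 tested genes were named in this way. Of the fixed genes, Hsd11b1 had too few reads to be tested. Genes named outside the rule were chosen after their values were seen, and the text says so.

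The fit was tested on simulated counts with the means and library sizes of the 6 libraries, in 5 runs with 200 changed genes each among 14508 genes. The changed genes were drawn from those with a mean CPM of at least 5. The edgeR test called 32.5% of genes changed 1.5-fold, 86.0% of those changed 2-fold and 98.5% of those changed 3-fold, and 5.50% of its calls were false. The Benjamini-Hochberg threshold is stricter where fewer genes change, so these shares do not hold for a comparison with few changed genes. In 20 simulated runs with independent genes, camera with the preset correlation called a list of 46 members shifted by -0.25 log2 in 20 runs. It called 2 of 635 tests of unshifted lists. Genes of a real list vary together, with an estimated correlation of 0.70 for S phase and mitosis genes. These shares of called lists therefore do not hold for the real data.

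Alternatives fixed in advance were RLE scaling, library totals alone, DESeq2 1.42.0, limma voom, no low count filter, a CPM of at least 1 in 3 libraries, a threshold of 0.10, removal of mitochondrially encoded genes, the sex of the library as a term, the replicate number as a block, an estimated correlation, fry, and leaving out each library. Added after the data were seen were scaling to the spike-in reads, removal of Gm42418, the sex term for lists, and an estimated correlation with GR-cKO replicate 3 left out. Xist and Y-linked genes called replicate 1 of each group female and the other 4 libraries male.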

Results

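The study asked how loss of the glucocorticoid receptor in heart muscle cells alters gene expression of the heart early after birth. Hearts of 3 control and 3 GR-cKO mice were profiled at postnatal day 7 by 3′ mRNA sequencing. Control replicates 1, 2 and 3 had 22999192, 19588639 and 19209410 reads, and GR-cKO replicates 1, 2 and 3 had 18135540, 20430717 and 20988286 reads. Between 18851 and 19673 mouse genes had a read in a library. Spike-in transcripts took 1.63 to 2.01% of reads. Pearson's r of log2 CPM, across genes, averaged 0.969 between libraries of a group and 0.970 between libraries of different groups. The closest pair of libraries differed by a chi-square of 10.1 per degree of freedom, far above sampling noise, so that no library was a copy of another.

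Nr3c1 (ENSMUSG00000024431), the gene of the glucocorticoid receptor, fell in GR-cKO hearts. It lies on the minus strand of chromosome 18 from 39410545 to 39519421 (GRCm38). It had 2618, 2558 and 1902 reads in control replicates 1, 2 and 3 and 1031, 1044 and 1045 reads in GR-cKO replicates 1, 2 and 3. Its level was 115 ± 15.8 CPM in control and 54.3 ± 4.47 CPM in GR-cKO hearts (SD, n = 3 each). The log2 fold change was -1.08 (SE 0.125, 95% interval -1.35 to -0.82), with an edgeR adjusted p of 0.00101. All 3 GR-cKO libraries lay below all 3 control libraries, as the labels have it. The tissue was whole heart, which also holds cells in which the gene was not targeted. The labels do not name the deleted exon, and 3′ reads that lie outside the deleted part do not measure the deletion itself.

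No other gene passed the threshold in the edgeR test of 14860 genes. At an unadjusted p under 0.05, 308 genes were higher and 316 lower, together 4.20% of those tested, where chance alone gives 743 genes. This split depended on the scaling, with 170 higher and 361 lower by library totals alone and 160 higher and 83 lower by spike-in scaling. DESeq2 called 1 gene higher, 9330158H04Rik, and 3 lower, Nr3c1, Trabd2b and Art1, and limma voom called 0 higher and Nr3c1 lower. The 3 GR-cKO libraries lay entirely on 1 side of the 3 controls for 1482 genes, or 9.97% of those tested, where chance gives 10%. The median SE of a log2 fold change was 0.207. For 72.2% of genes the 95% interval excluded a 2-fold change in either direction, and for 47.8% it excluded a 1.5-fold change.

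After Nr3c1, the smallest p-values belonged to Trabd2b, which encodes a membrane protease that cleaves Wnt proteins, and Art1, which encodes a muscle ADP-ribosyltransferase. Trabd2b (chromosome 4, 114406724 to 114615098, plus strand) was at 47.4 ± 0.785 CPM in control and 26.7 ± 3.64 CPM in GR-cKO hearts (SD, n = 3 each), a log2 fold change of -0.83 (SE 0.138, edgeR adjusted p = 0.0748). DESeq2 gave it an adjusted p of 0.000276, and edgeR without GR-cKO replicate 3 gave 0.0154. Art1 (chromosome 7, 102101743 to 102113933, plus strand) was at 23.04 ± 2.92 and 12.1 ± 0.485 CPM, a log2 fold change of -0.92 (SE 0.172, edgeR adjusted p = 0.190, DESeq2 adjusted p = 0.00219). The long non-coding RNA 9330158H04Rik was at 14.7 ± 1.76 and 27.5 ± 7.18 CPM, a log2 fold change of 0.90 (SE 0.188, edgeR adjusted p = 0.509, DESeq2 adjusted p = 0.0425). Art1 and 9330158H04Rik overlap genes on the opposite strand, Chrna10 and Chrm2 among them, so their counts are uncertain where strand was not used.

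The other 6 genes of smallest p had edgeR adjusted p-values of 0.998. Ckmt2, the mitochondrial creatine kinase of striated muscle, was at 682 ± 56.7 CPM in control and 475 ± 61.7 CPM in GR-cKO hearts (SD, n = 3 each). Acta2, the actin of smooth muscle and of immature heart muscle, was at 807 ± 106 and 1103 ± 18.6 CPM. Jund, a member of the AP-1 transcription factors, was at 67.4 ± 7.06 and 101 ± 25.0 CPM. Mt2, a metallothionein, was at 30.2 ± 2.97 and 18.9 ± 3.43 CPM. Aldh7a1, an enzyme of lysine breakdown whose gene overlaps Phax, was at 23.9 ± 2.70 and 14.6 ± 1.61 CPM. Rps6, a ribosomal protein gene with many near-identical pseudogene copies and so an uncertain count, was at 19.1 ± 1.94 and 11.01 ± 1.64 CPM.

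**Figure D1:**
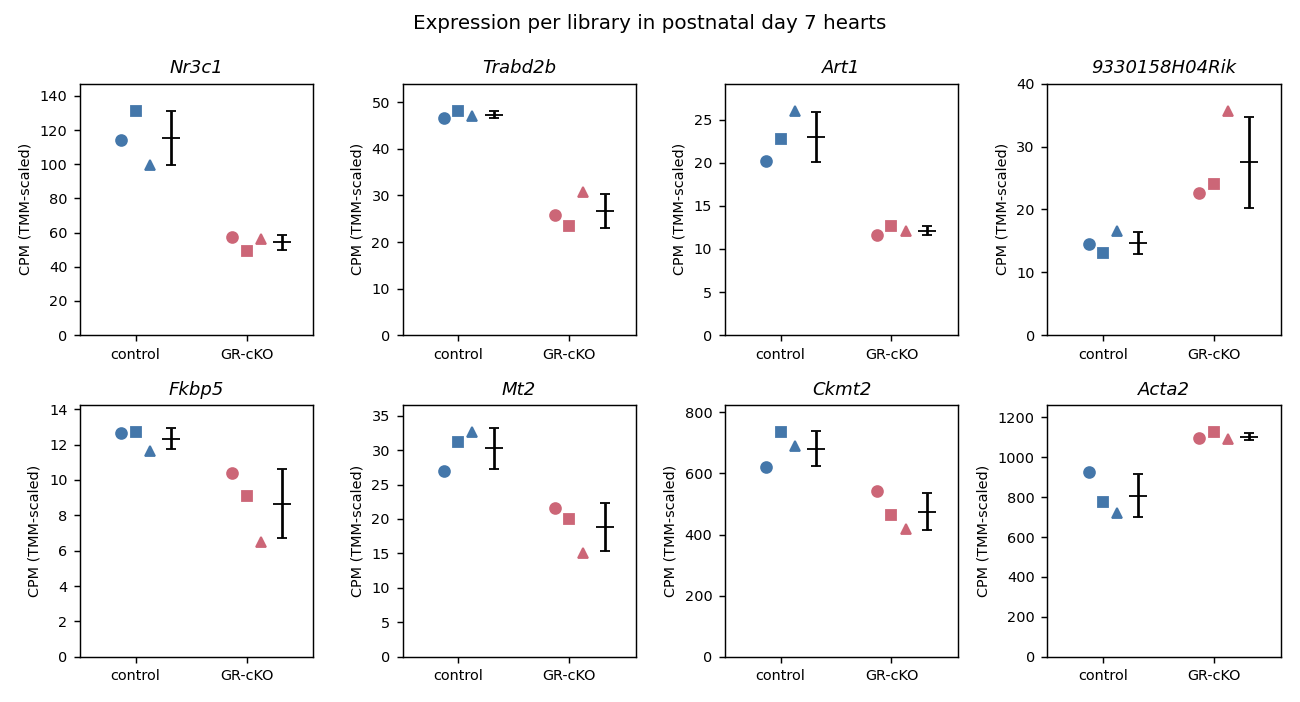
TMM-scaled CPM (vertical axes) of 8 genes in the 3 control (blue) and 3 GR-cKO (red) hearts, where circles, squares and triangles are replicates 1, 2 and 3 and black bars are the mean ± SD. Nr3c1 lay at 99.7 to 131 CPM in control and 49.2 to 57.6 CPM in GR-cKO hearts, and it alone of the 8 passed the edgeR threshold.

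Genes known to respond to glucocorticoids fell as a list. Of the 38 tested members 28 had a negative and 10 a positive log2 fold change, with a median of -0.11 (camera adjusted p = 0.0472), but the adjusted p was 0.814 with an estimated correlation. None of the 33 lists passed in that form. No member passed over all genes, and 1 member, Mt2, was lower when adjusted over the list alone (adjusted p = 0.0237). Mt1, another metallothionein, was at 187 ± 33.2 CPM in control and 139 ± 15.9 CPM in GR-cKO hearts (SD, n = 3 each). Fkbp5, a co-chaperone of the receptor and a standard glucocorticoid target, was at 12.3 ± 0.601 and 8.66 ± 1.98 CPM, a log2 fold change of -0.51 (SE 0.220). Pdk4, which restrains glucose oxidation, was at 146 ± 37.1 and 103 ± 28.6 CPM. Other classical targets lay closer together, with Tsc22d3 at 115 ± 6.87 and 107 ± 13.5 CPM (log2 fold change -0.10, 95% interval -0.35 to 0.15) and Klf9 at 219 ± 23.9 and 195 ± 45.8 CPM. Per1, a target that is also a clock gene, was at 38.7 ± 15.2 and 34.6 ± 23.1 CPM. With each library left out, log2 fold changes ran from -0.21 to -0.03 for Tsc22d3, -0.37 to -0.04 for Klf9 and -0.86 to 0.17 for Per1. Each was lowest without GR-cKO replicate 3. None of these single genes passed the edgeR test over all genes. The list scores were 0.12, 0.13 and 0.00 in control replicates 1, 2 and 3 and -0.16, -0.22 and 0.12 in GR-cKO replicates 1, 2 and 3. The camera adjusted p was 0.000342 without GR-cKO replicate 3, and 0.466 there with an estimated correlation. It was 0.0374 without control replicate 3, and 0.119, 0.129, 0.341 and 0.382 without control replicates 1 and 2 and GR-cKO replicates 1 and 2.

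Genes of other parts of glucocorticoid signalling gave no call. Nr3c2, the mineralocorticoid receptor gene, was at 5.45 ± 1.09 CPM in control and 4.62 ± 1.22 CPM in GR-cKO hearts (SD, n = 3 each). Hsd11b1, whose enzyme regenerates active glucocorticoid, had 0 to 12 reads per library and was not tested.

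The main lists of energy metabolism, complex I and fatty acid uptake and oxidation, did not pass. The list of respiratory chain complexes II to V, which was not a main list, fell. Of its 43 tested members 30 were lower and 13 higher, with a median log2 fold change of -0.08 (camera adjusted p = 0.0472), but the adjusted p was 0.814 with an estimated correlation. No member passed, either over all genes or adjusted over the list alone. Atp5j, a subunit of ATP synthase, was at 737 ± 97.7 CPM in control and 564 ± 71.0 CPM in GR-cKO hearts (SD, n = 3 each). Uqcrfs1, the iron-sulfur subunit of complex III, was at 567 ± 38.2 and 460.4 ± 25.1 CPM, and Cycs, cytochrome c, was at 133 ± 4.45 and 109 ± 12.7 CPM. The call ended without control replicate 2 (adjusted p = 0.408), GR-cKO replicate 1 (0.311) or GR-cKO replicate 2 (0.201), and with spike-in scaling (0.325). Control replicate 2, which had the highest score on this list (0.12), also had the highest level of the brown fat gene Ucp1, named after its values were seen, at 89.2 CPM against 0 to 18.8 CPM in the other 5 hearts.

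The other metabolic lists did not pass. Complex I had 23 of 37 members lower (median -0.05, camera adjusted p = 0.499). The tricarboxylic acid cycle and pyruvate oxidation list had a median of -0.09 (adjusted p = 0.0801), ketone body and branched chain amino acid oxidation -0.12 (0.115), glycolysis and lactate transport -0.03 (0.730) and regulators of mitochondrial biogenesis -0.01 (0.579). On the list of mitochondrially encoded genes, which holds 13, all 8 tested members were lower, with a median of -0.16 (adjusted p = 0.102). All genes of the mitochondrial genome, on that list or not, took 7.01 ± 0.105% of reads in control and 6.51 ± 0.240% in GR-cKO hearts (SD, n = 3 each, exact permutation p = 0.1, the smallest this design can give). Fatty acid uptake and oxidation had 18 of 33 members lower, a median of -0.03 and an adjusted p of 0.254. For this list GR-cKO replicate 3 opposed the other GR-cKO hearts, with scores of -0.04, -0.21 and 0.14 in GR-cKO replicates 1, 2 and 3. Without GR-cKO replicate 2 the direction turned upward (adjusted p = 0.862). Without GR-cKO replicate 3 the list was lower with an adjusted p of 0.000401, but 0.767 with an estimated correlation. Without GR-cKO replicate 3 the tricarboxylic acid cycle list (0.0165) and the mitochondrially encoded genes (0.0427) also passed, but the adjusted p was 0.696 for both with an estimated correlation. Ppargc1a, the main coactivator of mitochondrial genes, was at 183 ± 9.89 and 175 ± 27.2 CPM in control and GR-cKO hearts (n = 3 each), a log2 fold change of -0.06 with a 95% interval of -0.32 to 0.20. That fold change ran from -0.20 without GR-cKO replicate 3 to 0.01 without GR-cKO replicate 2.

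Genes of S phase and mitosis fell as a list, and this rested on 1 heart. Of the 46 tested members 38 were lower and 8 higher, with a median log2 fold change of -0.24 (camera adjusted p = 9.97e-05), but the adjusted p was 0.814 with an estimated correlation. No member passed over all genes or adjusted over the list alone. The list scores were 0.16, 0.18 and 0.06 in control replicates 1, 2 and 3 and 0.25, 0.01 and -0.66 in GR-cKO replicates 1, 2 and 3. Without GR-cKO replicate 3 the direction turned upward and the adjusted p was 0.965. In the same library the transcript Gm42418, which overlaps ribosomal RNA sequence and was named after its values were seen, took 10.9% of reads, against 5.47 to 7.69% in the other 5. Aurkb, a mitotic kinase, was at 5.37 ± 0.604 CPM in control and 3.21 ± 1.11 CPM in GR-cKO hearts (SD, n = 3 each). Ccnb2, a mitotic cyclin, was at 14.9 ± 2.07 and 9.91 ± 3.80 CPM, and Mcm4, part of the replicative helicase, was at 36.1 ± 6.58 and 26.4 ± 7.27 CPM. Mki67, a general marker of cycling cells, was at 26.7 ± 3.98 and 26.0 ± 9.58 CPM, with a 95% interval of -0.54 to 0.46 around a log2 fold change of -0.04. That fold change ran from -0.30 without GR-cKO replicate 1 to 0.22 without GR-cKO replicate 3. Ccnd2, a cyclin of fetal heart muscle, was at 1113 ± 114 and 1274 ± 35.8 CPM. Cell cycle inhibitors and regulators of cell cycle exit had a median of -0.06 (adjusted p = 0.720).

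**Figure D2:**
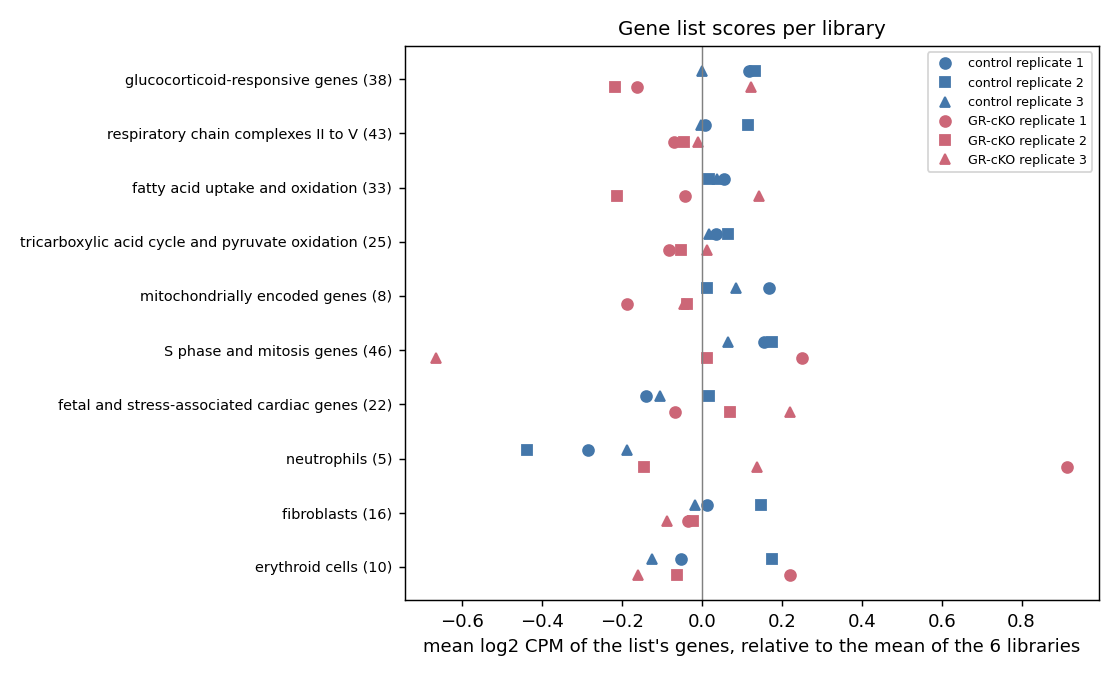
Scores of 10 gene lists (number of tested genes in brackets) in each of the 6 hearts, where the horizontal axis is the mean log2 CPM of a list's genes relative to the mean of all libraries, blue is control, red is GR-cKO, and circles, squares and triangles are replicates 1, 2 and 3. GR-cKO replicate 3 lay at -0.66 on the S phase and mitosis list and GR-cKO replicate 1 at 0.91 on the neutrophil list.

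Genes of the contractile apparatus and of the fetal heart programme gave no call. Myh6, the adult myosin heavy chain of the mouse heart, was at 10869 ± 356 CPM in control and 11843 ± 2364 CPM in GR-cKO hearts (SD, n = 3 each). Myh7, the fetal myosin heavy chain, was at 98.1 ± 30.5 and 150.5 ± 108 CPM, and its highest value, 274 CPM, was that of GR-cKO replicate 3. The natriuretic peptide genes Nppa (1577 ± 402 and 1432 ± 139 CPM) and Nppb (8.75 ± 1.23 and 11.2 ± 6.15 CPM) did not pass. The mature sarcomere list had a median log2 fold change of 0.12 (camera adjusted p = 0.428, and 0.814 with an estimated correlation). It passed upward without GR-cKO replicate 2 (0.0341) and turned downward without GR-cKO replicate 3 (0.827). Fetal and stress-associated cardiac genes had 15 of 22 members higher and a median of 0.17 (adjusted p = 0.0801), and Acta2 was higher when adjusted over the list alone (adjusted p = 0.0185). This list passed without control replicate 2 (0.0475) or GR-cKO replicate 1 (0.0488), and on all 6 hearts its adjusted p was 0.667 with an estimated correlation. Calcium handling and ion channel genes had a median of 0.02, a mean of -0.09 and a downward test (adjusted p = 0.987).

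Markers of other cell types showed 1 call, a rise of the neutrophil list. Of the 12 markers on the list 5 had enough reads for a test. All 5 were higher, with a median log2 fold change of 0.69 (camera adjusted p = 0.0235), but the adjusted p was 0.667 with an estimated correlation. No member passed over all genes, and S100a8 and Ngp were higher when adjusted over the list alone. S100a8, a calcium-binding protein of neutrophils, was at 7.78 ± 0.822 CPM in control and 12.6 ± 0.429 CPM in GR-cKO hearts (SD, n = 3 each). Its partner S100a9 was at 4.17 ± 1.61 and 6.07 ± 2.54 CPM, and Ngp, a granule protein, was at 0.644 ± 0.310 and 2.07 ± 1.06 CPM. Control libraries had Ngp at only 0.411 to 0.996 CPM, and a gene of few reads can pass the count filter through the group where it is higher. Without that filter the camera adjusted p of the list was 0.178. The list scores were -0.28, -0.44 and -0.19 in control replicates 1, 2 and 3 and 0.91, -0.14 and 0.14 in GR-cKO replicates 1, 2 and 3. Without GR-cKO replicate 1 the adjusted p was 0.308.

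The remaining marker lists did not pass. Their median log2 fold changes were -0.10 for fibroblasts (camera adjusted p = 0.152), -0.06 for endothelial cells (0.516), 0.03 for macrophages (0.520), 0.12 for lymphocytes and thymus (0.414), -0.06 for erythroid cells (0.885) and -0.14 for nerve and Schwann cells (0.720). Mural cell markers had a median of -0.03 but an upward test (0.885). Epicardial and mesothelial markers had a median of 0.21 (0.0801) and passed without control replicate 2 (0.0366) or GR-cKO replicate 3 (0.0128) and with the sex of the library as a term (0.0409). With an estimated correlation the adjusted p of this list was 0.814 on all 6 hearts and 0.767 without GR-cKO replicate 3. The lymphocyte list passed without control replicate 2 (0.0409), and on all 6 hearts its adjusted p was 0.814 with an estimated correlation. Markers of neighbouring or attached tissue had medians of -0.42 for adipose tissue (0.484) and 0.26 for skeletal muscle (0.520). Atrial markers had a median of -0.14 (0.254) and passed without control replicate 1 (0.0422) or GR-cKO replicate 2 (0.0334), and on all 6 hearts their adjusted p was 0.814 with an estimated correlation. Ventricular markers had a median of 0.03 and a downward test (0.885), and Ckmt2 was lower when adjusted over that list alone (adjusted p = 0.00348).

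Of the signalling lists none passed. Circadian clock genes had a median of 0.04 (camera adjusted p = 0.349), and Nr1d1, named after its value was seen, was at 6.59 CPM in control and 12.4 CPM in GR-cKO hearts (adjusted over the list alone, edgeR adjusted p = 0.0318). YAP target genes had a median of 0.08 (0.499), interferon response genes 0.02 (0.579) and NF-kB targets and cytokines 0.05 (0.751). Handling and heat shock genes had a median of 0.10 (0.499), with Jund higher when adjusted over the list alone (adjusted p = 0.0225). Cytosolic ribosomal protein genes had a median of 0.02 and a downward test (0.824), with Rps6 lower when adjusted over the list alone (adjusted p = 0.0244). Acta2 among the mural markers (0.0101) and Vwf among the endothelial markers (0.0490), the latter named after its value was seen, also passed over their list alone. None of the genes that passed over a list alone passed over all genes in the main edgeR fit.

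**Figure D3:**
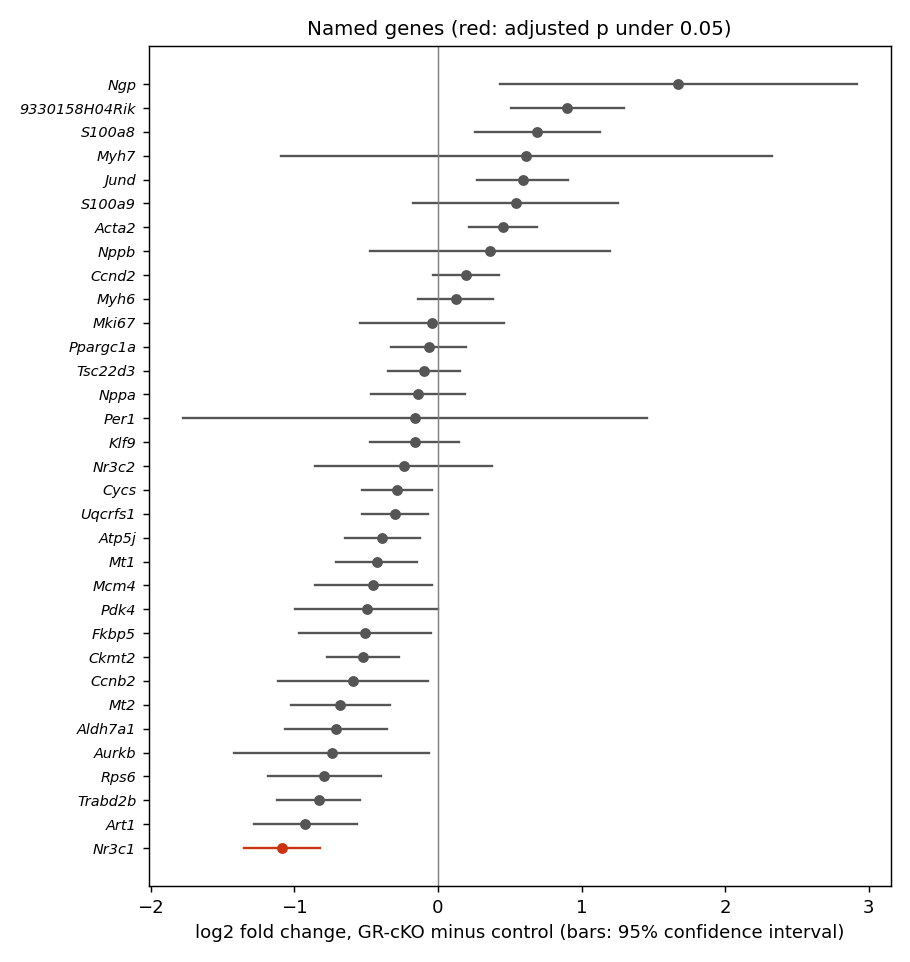
Log2 fold changes, GR-cKO minus control, of the 33 tested named genes (horizontal axis), with 95% confidence intervals as bars. Nr3c1, in red at -1.08, is the gene past an adjusted p of 0.05 in the edgeR test.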

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

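Scaling to spike-in reads, removal of Gm42418, the sex term for lists, and the estimated correlation with GR-cKO replicate 3 left out were chosen after the data were seen. Nr3c1 was lower and past the threshold in 17 of 17 alternatives, with log2 fold changes of -1.18 to -0.98 and adjusted p-values of 2.09e-12 to 0.0295. Counts of called genes moved more. Genes lower numbered 2 with library totals alone, 3 with DESeq2, 6 without a low count filter, 2 at a threshold of 0.10, and 1 to 2 when each library was left out, with Gm28438 added without GR-cKO replicate 2 and Trabd2b added without GR-cKO replicate 3. Genes higher numbered 1 with DESeq2 and 4 without a filter (9330158H04Rik, Jund, Sftpc and Tmem267). The cause was not tested, except that a looser threshold admits more genes. The number of lists past the threshold, 4 of all 33, was 0 with an estimated correlation, 0 by fry, 1 without a filter and 1 with a CPM of at least 1 (S phase and mitosis in both), 0 with an estimated correlation and GR-cKO replicate 3 left out, and 2 to 7 when each library was left out. The 2 lists without GR-cKO replicate 1 held S phase and mitosis of those 4, and the 7 without GR-cKO replicate 3 held the other 3. With an estimated correlation the adjusted p was 0.814 for glucocorticoid-responsive genes, for complexes II to V and for S phase and mitosis, and 0.667 for neutrophils. By fry it was 0.633, 0.633, 0.872 and 0.603. With an estimated correlation and GR-cKO replicate 3 left out it was 0.466, 0.914, 0.987 (with the direction turned upward for S phase and mitosis) and 0.696. Without a filter it was 0.158 for glucocorticoid-responsive genes and for complexes II to V and 0.178 for neutrophils, and with a CPM of at least 1 it was 0.0846 for glucocorticoid-responsive genes and 0.0668 for complexes II to V, while the neutrophil list had too few members for a test. Complexes II to V gave 0.0713 with the sex term and 0.325 with spike-in scaling. With each library left out, adjusted p-values ran from 0.000342 to 0.382 for glucocorticoid-responsive genes, 0.0122 to 0.408 for complexes II to V, 0.0128 to 0.308 for neutrophils, 0.000401 to 0.862 for fatty acid oxidation, and 1.25e-12 to 0.965 for S phase and mitosis, where the highest came without GR-cKO replicate 3 and with the direction turned. Estimated correlations use how genes vary together between hearts, and that of the S phase and mitosis list was 0.70. Correlation was not the whole cause of the larger p-values, since this form also rests on the few residual degrees of freedom of 6 libraries. Mitochondrially encoded genes had an estimated correlation of -0.091, yet their unadjusted camera p rose from 0.0247 to 0.0808. How often this form of camera calls a shifted list was not simulated, so a call lost there does not show that a list did not move. For the other changes of call the cause was not tested. Of the 32 other named genes, 5 passed in any alternative and 6 changed sign, and 12 lists passed and 17 changed sign in any. Signs of results that had not passed were not counted as reversals.

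No pairing of the libraries by replicate number was seen, but 3 libraries per group cannot exclude shared litters or batches. Sex-linked genes were left out of this check, and replicate 1 of each group was female. Deviations of libraries with the same number correlated at -0.0152, 0.0369 and -0.00353, and only control replicate 2 correlated best with its own number. With the replicate number as a block, 0 genes were higher and 1 lower, and 3 lists passed (S phase and mitosis, neutrophils, and epicardium and mesothelium). Without the block, the camera adjusted p-values of these lists with an estimated correlation were 0.814, 0.667 and 0.814. With the block, glucocorticoid-responsive genes had an adjusted p of 0.0552 and complexes II to V of 0.0766.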

Other observations

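Tests of the explanations below, other than the counts of splits, were chosen after the results were seen, and so were the genes named here. GR-cKO replicate 3 differed from the other 5 hearts in several gene programmes. Ankrd1, a stretch-responsive cardiac gene, was at 1989 CPM there against 811 to 1078 CPM in the other 5. Irs2, an adaptor of insulin signalling, was at 31.9 CPM against 8.48 to 14.6 CPM. The immediate early genes Jun (269 against 98.2 to 139 CPM) and Nr4a1 (26.6 against 10.4 to 13.8 CPM) were also highest there. Besides S phase and mitosis, 7 lists had a mean log2 difference from the other 5 beyond 2 SE over genes. It was 0.42 for handling and heat shock genes (SE 0.166), 0.27 for clock genes (SE 0.127), 0.19 for mature sarcomere genes (SE 0.0622) and 0.17 for fatty acid uptake and oxidation (SE 0.0706). It was -0.25 for glycolysis (SE 0.115), -0.19 for erythroid genes (SE 0.0601) and -0.17 for atrial markers (SE 0.0805). These are values of 1 heart with no test.

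Traces of neighbouring tissue differed between hearts. Ucp1, specific to brown fat, was at 6.77, 89.2 and 0.419 CPM in control replicates 1, 2 and 3 and at 0, 18.8 and 3.92 CPM in GR-cKO replicates 1, 2 and 3. Car3, abundant in fat and skeletal muscle, was at 9.57, 25.6, 2.10, 3.40, 20.9 and 8.54 CPM in the same order. Sftpc, a lung surfactant gene, had 0 reads in each control library and 7, 3 and 43 reads in GR-cKO replicates 1, 2 and 3, and edgeR without a low count filter called it higher.

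The fall of S phase and mitosis genes came from GR-cKO replicate 3, where 45 of 46 members lay below the mean of the other 5 hearts, by a mean log2 difference of -0.80 (SE 0.0624). Ube2c, a mitotic ubiquitin enzyme, was at 10.3 CPM there against 71.0 to 86.5 CPM in the other 5, and without this heart the adjusted p was 0.965. Fewer non-muscle cells would lower their markers alike. Of the fibroblast, endothelial, mural and macrophage lists the lowest mean difference was -0.105 (SE 0.0782), which argues against this for that heart. The SEs in this paragraph are over genes, which vary together, and do not cover the spread between hearts. A more mature heart may also cycle less, but its fetal and stress-associated genes had a mean difference of 0.265 (SE 0.142), against 0.19 (SE 0.0622) for mature sarcomere genes, which leaves this open. The library of this heart also stood apart, with the lowest TMM factor of the 6 (0.904) and the highest share of reads in its 10 most abundant genes (23.7%). With scaling other than TMM, camera at the preset correlation still had the S phase and mitosis list lower. The adjusted p was 0.00167 by library totals alone, 8.86e-05 by RLE and 0.000255 by spike-in reads. Whether the high share of reads in the most abundant genes bears on the list was not tested. A difference in the age, health or handling of this animal stays open, and genotype was not separable from 1 animal.

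The neutrophil list was higher in GR-cKO hearts, most of all in GR-cKO replicate 1. Without that heart the camera adjusted p was 0.308, and on all 6 hearts it was 0.667 with an estimated correlation. More blood left in the hearts could raise the list, but then erythroid genes would rise alike. Their mean log2 fold change was -0.0029 (SE 0.0562) against 0.724 (SE 0.268) for the neutrophil genes. The SEs in this paragraph are over genes, which vary together, and do not cover the spread between hearts. GR-cKO replicate 1 had the highest erythroid score of the 6 hearts. Its mean log2 difference from the other 5 was 0.265 (SE 0.0749) for erythroid genes against 1.10 (SE 0.215) for neutrophil genes. This argues against blood of usual composition as the whole cause in that heart. More blood as part of the rise in that heart, and a higher share of neutrophils in blood or tissue, by genotype or in single animals, stay open.

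The lower level of complexes II to V in GR-cKO hearts may partly reflect brown fat attached to control replicate 2, since brown fat is rich in mitochondria. Over the 6 hearts the score of this list and the adipose score had a Pearson's r of 0.716 (exact permutation p = 0.0944, Benjamini-Hochberg adjusted 0.189 over both coefficients) and a Spearman's rho of 0.6 (exact permutation p = 0.242, adjusted 0.242). Without the 2 hearts farthest from the median adipose score r was -0.480, so the relation rests on those hearts. Other mitochondrial lists were mixed. Among the controls, replicate 2 had the highest score for complex I (0.09), the tricarboxylic acid cycle (0.07) and ketone body and branched chain amino acid oxidation (0.09). It had the lowest for mitochondrially encoded genes (0.01) and for fatty acid uptake and oxidation (0.02). The camera adjusted p of complexes II to V was 0.408 without control replicate 2. The call also ended without GR-cKO replicate 1 (0.311) or GR-cKO replicate 2 (0.201), so its loss was not particular to the heart with the most Ucp1. Brown fat and an effect of genotype cannot be told apart here, because the relation did not pass and 6 hearts are few.

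The 6 hearts can be split into 2 groups of 3 in 10 ways, which cannot give a share under 0.05. As many genes as in the real split (1) were called in 3 of the 10 splits, with at most 1 in another split. As many lists (4) were called in 6 splits, with up to 10 in another. A camera p as small as the real one was found for S phase and mitosis in 6 splits (real 3.02e-06, smallest other 3.26e-15), for glucocorticoid-responsive genes in 3 (0.00573, smallest other 9.36e-05), for complexes II to V in 2 (0.00511, smallest other 0.00329) and for neutrophils in 1 (0.00142, smallest other 0.0653). The split with 10 lists joined control replicates 1 and 3 with GR-cKO replicate 1, so list calls at the preset correlation also follow differences between single hearts.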
